A study of Danio rerio with 12 samples.

How the data were processed

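Caudal fins of adult zebrafish were taken before amputation (0 days post amputation, dpa) and at 2 dpa, 3 dpa and 10 dpa. Each stage had 3 libraries, 12 in all, and each library was made from RNA of a pool of 6 fish, per the labels. RNA was extracted with a Macherey-Nagel column kit without its carrier RNA, per the labels' protocols. Libraries were made with Lexogen's SENSE mRNA-Seq kit and sequenced on a SOLiD Wildfire instrument, per the same protocols. Such libraries are selected for polyadenylated RNA, so transcripts without a poly(A) tail are underrepresented. The aligner, the counting program, the genome build, the annotation release and any use of strand in counting are not given in the sources used here. Counts of near-identical paralogs and of overlapping or antisense genes are therefore uncertain. Whether the same fish were sampled at more than 1 stage is not stated, and p-values measure the spread between pools.

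The values analysed are raw counts per Ensembl gene identifier, deposited as 1 table with 1 column per library. The columns are named after alignment files, 1 per library, per the file headers. The values are whole numbers whose totals differ between libraries, from 8833337 to 22843743. Columns were assigned to samples by the column name quoted in each sample's labels. Symbols came from a table of gene names, in which 21939 of the 33737 identifiers (65.0%) had one, and these carried 89.0% of the counts. Of the identifiers, 3206 share their symbol with another. These and symbols in capital letters (10409), which follow the human gene, do not say which zebrafish paralog is meant. No coordinates were used.

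The 4 stages were the groups. Counts were analysed with edgeR (version 4.0.16, R version 4.3.3) with TMM normalisation, filterByExpr at a count minimum of 10 and the robust quasi-likelihood test. All 12 libraries entered 1 fit with stage as the only term, which left 16612 genes and a biological coefficient of variation of 26.9%. Comparisons were 2, 3 and 10 dpa against 0 dpa, 3 against 2 dpa and 10 against 3 dpa, plus an F test over the 4 stages. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to rise or fall, with no threshold on fold. The spread between replicates exceeded counting error in every pair of a stage, so no intervals of counting error are given. Levels in CPM use library sizes multiplied by the TMM factors.

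Comparisons, tests, 24 gene lists of fin tissues and processes, the rule for naming genes and the alternatives were fixed before the data were examined, except where said otherwise. The lists came from general knowledge, and some genes stand on more than 1. Of the 856 members written, 536 were matched by symbol and 141 were not matched. The other 179 were matched by a capital symbol with the paralog letter removed, a rule set after seeing the symbols and before any test. The 23 lists with at least 4 tested members were tested with camera in limma (version 3.58.1), two-sided, on log2 CPM (prior count 2) with the preset correlation of 0.01. Adjustment was over all 115 results. Camera compares a list with the other genes, and 60 results passed. With an estimated correlation camera passed 0, with 18 at an unadjusted p under 0.05. Fry, which tests whether members move on balance one way, passed 54 of the 115. The actinotrichia list, with 3 members, is described by its members.

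Genes were named by rule. They had a symbol, an adjusted p under 0.05, at least 10 counts in each library of the higher group and no overlap in CPM between the groups. Of these, the 12 largest rises and 12 largest falls against 0 dpa were taken, and 6 and 6 for the later comparisons. From each list came up to 3 passing members with the largest rise and 3 with the largest fall, or the 2 of smallest p where none passed. Not all are printed, and 1 of the largest changes is not reported here. Among them, genes that held under the alternatives were preferred, and that choice was made after their values were seen. Folds are printed only where leaving out any 1 library moved them by less than 1.5 times, and levels otherwise.

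Replicate numbers pair the libraries by label, because a field of the sample names (L01, L02 or L03), read as a shared sequencing batch, follows the number. What that field marks is not spelled out, and the part of the name before it is the same for all 12 libraries. The correlations that follow cannot tell a sequencing batch from anything else that follows the replicate number. Deviations from the stage means had a median r across genes of 0.119 between same-numbered libraries (18 pairs, -0.225 to 0.478, 11 over 0.1). The median was -0.0442 for the 36 other pairs, and 9 of 12 libraries correlated best with one of their own number.

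Alternatives were RLE normalisation, no filter on low counts, a replicate block, a fit of the compared groups only, DESeq2 (version 1.42.0), leaving out each library in turn and camera with an estimated correlation. Leaving out the 4 libraries of replicate number 2, called the second sequencing batch, was added after seeing the data. Ranges printed for lists cover the settings run with the preset correlation. For a described list that did not pass, the number of these settings under which it passed is given where it is above 0. Differential expression was checked on simulated data for 2 against 0 dpa (15929 genes). It recovered 14.0% of 100 genes changed by a log2 fold of 1 and 87.0% of 100 changed by a log2 fold of 2. No other genes were changed there, whereas 47.1% of tested genes passed in the real comparison. The adjusted p depends on that share, so these percentages do not give the power of the real test. Unchanged genes made up 8.18% of the 110 genes called. Camera called the raised list there and 0 of 20 random lists. That list was built from raised genes, and all genes were simulated independently of each other. The camera check therefore does not test the preset correlation or calls on lists of correlated genes. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.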

Results

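Polyadenylated RNA from the caudal fin of adult zebrafish (Danio rerio, AB-Tu strain) was sequenced before amputation (0 days post amputation, dpa) and at 2, 3 and 10 dpa. The caudal fin holds bony rays, connective tissue, blood vessels, nerves, pigment cells and a layered epidermis, and regrows after amputation from a mass of proliferating cells, the blastema. Each library was made from a pool of 6 fish, and each stage had 3 libraries, 12 in all. The table of counts held 33737 Ensembl gene identifiers, of which 7599 had 0 counts in every library, and 16612 passed the expression filter. Total counts per library ran from 8833337 to 22843743. Levels are given below in CPM, counts scaled by library size after TMM normalisation, as mean ± SD over n = 3 libraries. Folds and log2 changes ± SE are edgeR's estimates. For gene lists, members not said to rise or fall did not pass, and a list adjusted p is that of camera.

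The libraries separated by stage on the first 2 principal components, which carried 55.9% and 16.3% of the variance. On the first component the 0 dpa libraries lay from -103 to -83.2, the 10 dpa libraries from -49.3 to -38.1, and the 2 and 3 dpa libraries from 49.9 to 87.0. On the second, 2 dpa replicate 2 stood at -4.83, apart from the other 2 dpa libraries (46.8 and 72.5) and on the side of the 3 dpa libraries (-34.0 to -26.9). Replicates of a stage differed by more than counting noise, with a chi-square per degree of freedom from 19.4 to 123, so no pair was one library deposited more than once. The largest value belonged to 2 dpa replicates 1 and 2. Spearman's rho across genes was 0.955 to 0.978 within a stage and 0.807 to 0.979 between stages.

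**Figure D1:**
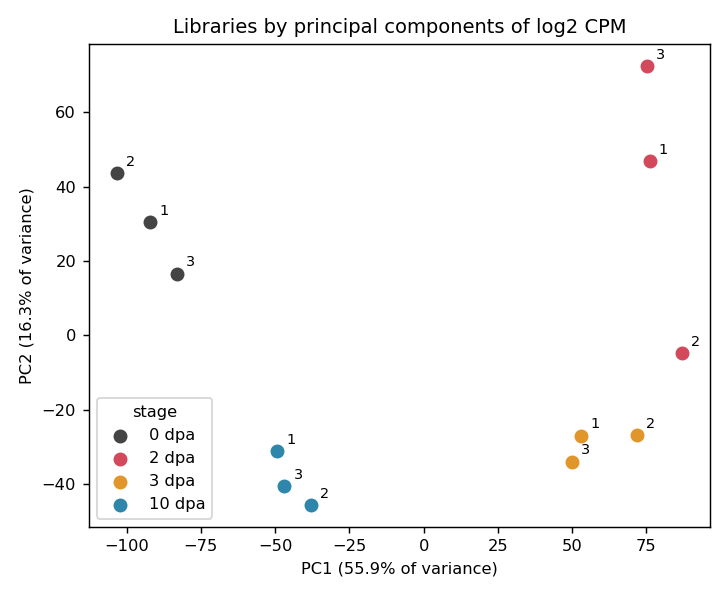
Each point is 1 library, coloured by stage and numbered by replicate, on the first (55.9% of variance) and second (16.3%) principal components of log2 CPM. The 0 dpa libraries lie at -83.2 or below on the first component and all 2 and 3 dpa libraries at 49.9 or above, while 2 dpa replicate 2 lies at -4.83 on the second component, between the other 2 dpa libraries and those of 3 dpa.

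Which genes changed at any stage was asked first. Transcript abundance differed among the 4 stages for 8090 of the 16612 tested genes (48.7%, edgeR quasi-likelihood F test). By their mean levels, 2970 of these genes stood highest in the uncut fin, 2032 at 2 dpa, 1826 at 3 dpa and 1262 at 10 dpa. Their lowest mean was at 0 dpa for 3264, at 2 dpa for 2766, at 3 dpa for 1442 and at 10 dpa for 618. The leptin gene lepb (ENSDARG00000045548) averaged 0.412 ± 0.571, 52.2 ± 14.0, 47.4 ± 12.3 and 3.81 ± 0.769 CPM at 0, 2, 3 and 10 dpa. The gene and1 (ENSDARG00000088514), which codes for a protein of the actinotrichia, the stiff fibrils at the fin tip, averaged 543 ± 358, 4401 ± 2333, 23619 ± 10583 and 5929.8 ± 2118 CPM. The glial and pigment cell regulator SOX10 averaged 27.2 ± 4.66, 0.960 ± 0.677, 2.56 ± 1.45 and 22.9 ± 2.19 CPM.

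**Figure D2:**
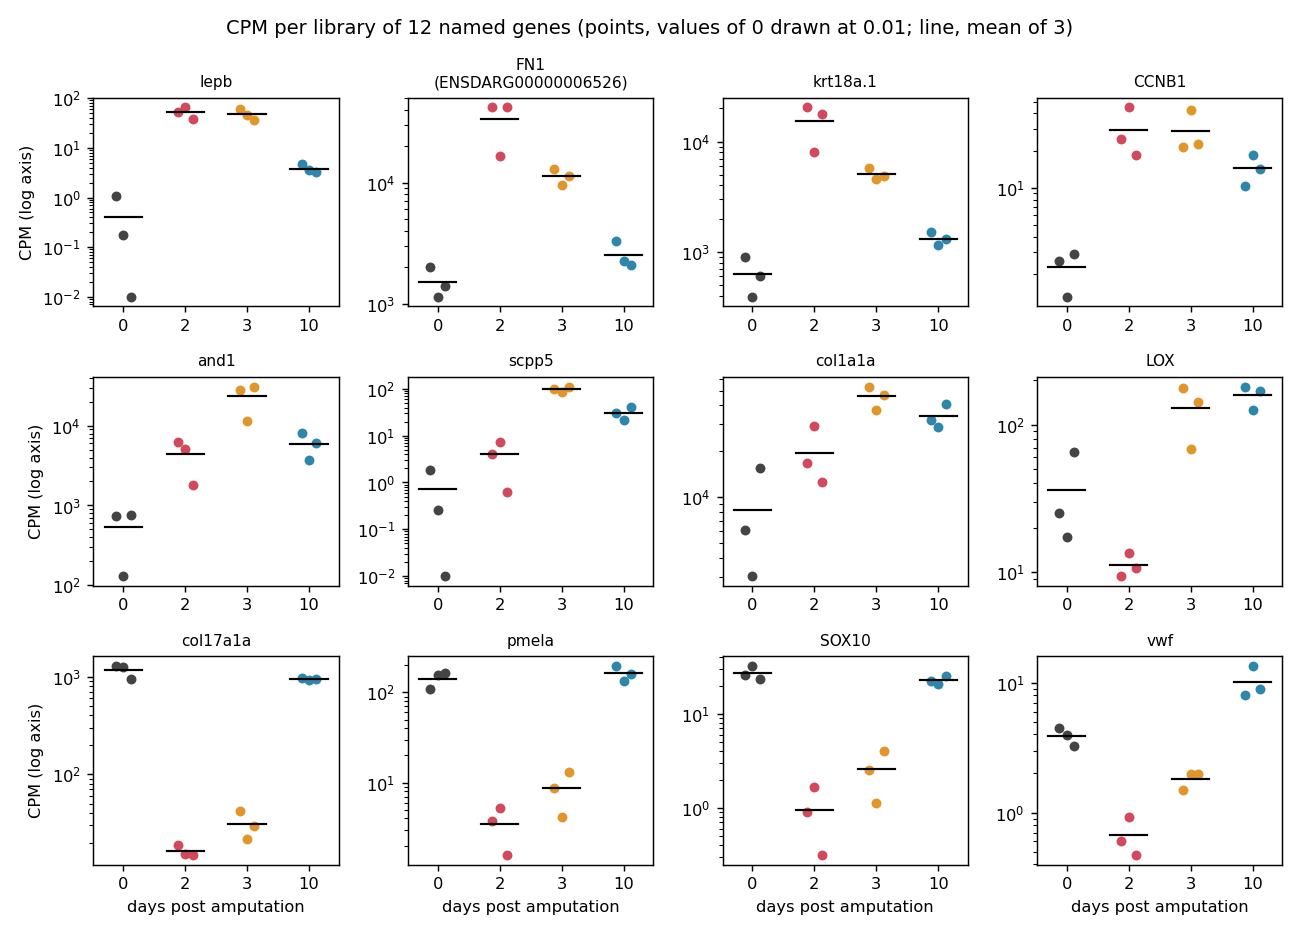
Each panel shows 1 gene at 0, 2, 3 and 10 dpa, with CPM on a log axis, 1 point per library (a value of 0 drawn at 0.01) and a line at the mean of 3 libraries. The mean of FN1 stands at 33375 CPM at 2 dpa against 1518 before amputation, that of and1 at 23619 CPM at 3 dpa, and that of SOX10 at 27.2 CPM before amputation, 0.960 at 2 dpa and 22.9 at 10 dpa.

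The comparison of 2 dpa with the uncut fin asked which transcripts differed early in regeneration. The largest rise by the naming rule was in ggt1a (ENSDARG00000023526), named for a gamma-glutamyltransferase (from 0.0834 ± 0.0819 to 15.9 ± 5.11 CPM, adjusted p = 8.78e-07). The leptin gene lepb reached 52.2 ± 14.0 CPM at 2 dpa against 0.412 ± 0.571 at 0 dpa (adjusted p = 1.32e-06). Transcripts of il11a (ENSDARG00000037859), an interleukin of the IL-6 family, rose 70.5-fold to 28.8 ± 8.46 CPM (log2 change 6.14 ± 0.36, adjusted p = 2.27e-07). Fibronectin 1 (FN1, ENSDARG00000006526), an early wound matrix protein, rose 22.0-fold to 33375 ± 14608 CPM. Tenascin C (TNC, ENSDARG00000021948), another matrix glycoprotein, rose 43.7-fold to 2337 ± 225 CPM. The membrane-bound protease gene adam8a rose from 18.1 ± 13.5 to 1059 ± 290.1 CPM, and coagulation factor V (f5) from 1.32 ± 1.69 to 95.8 ± 53.9 CPM. Among the largest falls, edn3b, an endothelin gene, went from 4.89 ± 2.24 to 0 ± 0 CPM, and GDF5, a growth factor of joints, from 11.9 ± 2.65 to 0.0335 ± 0.0580 CPM. The genes ptgdsb.1 (ENSDARG00000027088) and ptgdsb.2 (ENSDARG00000071626), named for prostaglandin D2 synthase, fell from 7436 ± 237 to 37.3 ± 23.0 CPM and from 675 ± 140.2 to 3.49 ± 1.98 CPM.

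Cell cycle, ribosome and secretory genes were higher at 2 dpa. Of the cell cycle list, 55 of 57 rose (55 adjusted over the list alone) (list adjusted p = 6.20e-19, and adjusted p = 0.263 with an estimated correlation). Its largest rises were in cyclin B1 (CCNB1), from 2.25 ± 0.843 to 29.3 ± 13.8 CPM, the spindle kinesin kif11, from 2.44 ± 1.44 to 30.3 ± 12.8 CPM, and the mitotic kinase aurka, from 0.928 ± 0.533 to 9.81 ± 2.36 CPM. Among ribosome biogenesis genes, 21 of 28 rose and 1 fell (23 and 1 adjusted over the list alone) (list adjusted p = 2.71e-05, and adjusted p = 0.443 with an estimated correlation). Nucleophosmin (npm1a) rose 4.03-fold, while the RNA helicase DDX21 fell from 143 ± 25.4 to 41.8 ± 4.43 CPM. For the secretory pathway, 35 of 41 rose and 1 fell (36 and 2 adjusted over the list alone) (list adjusted p = 2.09e-10, and adjusted p = 0.144 with an estimated correlation). The endoplasmic reticulum chaperone HYOU1 went from 18.3 ± 5.35 to 141 ± 66.3 CPM, and SEC23B, a coat protein of transport vesicles, fell from 298 ± 55.3 to 111 ± 6.35 CPM. Blastema and fin outgrowth signals did not pass as a list by camera, although 26 of 60 rose and 16 fell (27 and 17 adjusted over the list alone) (list adjusted p = 0.0594, 0.0135 to 0.102 over 10 other settings of which 4 passed, and adjusted p = 0.599 with an estimated correlation). Fry did pass them (unadjusted p = 2.34e-04), with a mean log2 change of 0.815 and a median of 0.283. Beside lepb and il11a, FGF20 (ENSDARG00000007356) rose from 1.33 ± 0.759 to 50.8 ± 24.2 CPM. The chemokine CXCL12 fell from 77.2 ± 13.0 to 8.66 ± 3.11 CPM, and CYP26B1, which degrades retinoic acid, from 222 ± 12.7 to 58.6 ± 20.6 CPM.

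Most matrix lists held both rises and falls at 2 dpa. Of the collagen maturation enzymes, 18 of 30 rose and 5 fell (19 and 5 adjusted over the list alone) (list adjusted p = 0.00598, and adjusted p = 0.650 with an estimated correlation). The collagen chaperone SERPINH1 (ENSDARG00000075954) rose 7.95-fold and the prolyl isomerase FKBP9 7.76-fold. The procollagen proteinase enhancer pcolceb fell from 236 ± 35.3 to 4.97 ± 1.64 CPM, and LOXL1, which cross-links elastin, from 37.9 ± 4.83 to 2.40 ± 0.866 CPM. With the second sequencing batch left out, a setting chosen after seeing the data, this list did not pass (adjusted p = 0.109, with 8.84e-04 to 0.109 over the settings with the preset correlation). Proteoglycans were lower as a list, where 2 of 25 rose and 12 fell (2 and 12 adjusted over the list alone) (list adjusted p = 0.00793, and adjusted p = 0.584 with an estimated correlation). The lubricin genes prg4a and prg4b fell from 931 ± 167 to 5.73 ± 3.00 CPM and from 12.2 ± 5.88 to 0.176 ± 0.0889 CPM, while the mimecan gene OGN (ENSDARG00000044132) was 4.97-fold higher. In the basement membrane list, 10 of 31 rose and 9 fell (10 and 9 adjusted over the list alone) (list adjusted p = 0.721, and adjusted p = 0.934 with an estimated correlation). There FREM2 and the nidogen NID2 rose 47.7-fold and 23.8-fold, whereas col17a1a, a collagen of hemidesmosomes, fell from 1160.4 ± 187 to 16.4 ± 2.24 CPM. Among the ECM glycoproteins, 6 of 32 rose and 11 fell (6 and 11 adjusted over the list alone) (list adjusted p = 0.318, 0.00668 to 0.651 over 10 other settings of which 2 passed, and adjusted p = 0.826 with an estimated correlation). Periostin (POSTN) fell from 82.8 ± 26.4 to 4.43 ± 2.56 CPM and CCN2, a connective tissue growth factor, from 209.7 ± 50.5 to 23.7 ± 8.81 CPM. Of the fibrillar collagens, 5 of 11 rose (5 adjusted over the list alone) (list adjusted p = 0.0566, 9.26e-04 to 0.803 over 10 other settings of which 4 passed, and adjusted p = 0.712 with an estimated correlation). Of the metalloproteinases and inhibitors, 13 of 30 rose and 6 fell (13 and 7 adjusted over the list alone) (list adjusted p = 0.248, and adjusted p = 0.712 with an estimated correlation).

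Markers of several differentiated cell types were lower at 2 dpa. Of the pigment cell list, 2 of 23 rose and 19 fell (2 and 19 adjusted over the list alone) (list adjusted p = 1.04e-07, and adjusted p = 0.272 with an estimated correlation). The melanosome fibril protein pmela fell from 142 ± 30.1 to 3.49 ± 1.82 CPM, and tyrosinase (TYR), the first enzyme of melanin synthesis, from 23.0 ± 5.77 to 0.662 ± 0.348 CPM. Of the nerve and glia markers, 1 of 16 rose and 10 fell (1 and 12 adjusted over the list alone) (list adjusted p = 0.00125, and adjusted p = 0.128 with an estimated correlation). Of these SOX10 fell from 27.2 ± 4.66 to 0.960 ± 0.677 CPM. In the endothelial and lymphatic list, 1 of 24 rose and 15 fell (1 and 16 adjusted over the list alone) (list adjusted p = 7.31e-05, and adjusted p = 0.399 with an estimated correlation). Von Willebrand factor (vwf) fell from 3.91 ± 0.628 to 0.667 ± 0.238 CPM, and the endothelial receptor GPR182 from 5.18 ± 0.886 to 0.693 ± 0.376 CPM. Epidermal keratins and junctions were lower as a list, where 5 of 39 rose and 17 fell (5 and 17 adjusted over the list alone) (list adjusted p = 0.0339, and adjusted p = 0.650 with an estimated correlation). Against that direction krt18a.1, a keratin of simple epithelia, rose 24.5-fold to 15397 ± 6557 CPM, while krt1-19d fell from 809 ± 107 to 136 ± 35.6 CPM. The epidermal list did not pass without 0 dpa replicate 1 (adjusted p = 0.0928), without 2 dpa replicate 2 (0.265) or with the second sequencing batch left out (0.130). Over the settings with the preset correlation its adjusted p ran from 0.00607 to 0.265. Of the goblet cell and ionocyte markers, 3 of 16 rose and 9 fell (4 and 9 adjusted over the list alone) (list adjusted p = 0.0646, 0.0205 to 0.139 over 10 other settings of which 3 passed, and adjusted p = 0.447 with an estimated correlation). Fry passed this list (unadjusted p = 4.75e-04). The mucin muc5.2 stood at 0.402 to 1.99 CPM at 2 dpa and 15.5 to 28.3 CPM at 0 dpa.

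Immune lists did not pass at 2 dpa. Of the macrophage and leukocyte markers, 7 of 31 rose and 12 fell (8 and 12 adjusted over the list alone) (list adjusted p = 0.349, and adjusted p = 0.712 with an estimated correlation). The apolipoprotein gene apoc1 rose from 1.95 ± 0.119 to 21.2 ± 14.0 CPM, the amino acid transporter SLC7A7 rose 8.36-fold, and the lymphocyte interleukin receptor il2rb fell from 66.0 ± 27.6 to 5.62 ± 3.14 CPM. Of the inflammatory mediators, 4 of 24 rose and 8 fell (4 and 10 adjusted over the list alone) (list adjusted p = 0.318, and adjusted p = 0.749 with an estimated correlation). Among those that rose were lepb and il11a, which also stand on the blastema list. Inducible nitric oxide synthase (NOS2, ENSDARG00000026925) fell from 786 ± 353 to 21.1 ± 16.9 CPM. Of the neutrophil markers, 2 of 13 rose and 3 fell (2 and 3 adjusted over the list alone) (list adjusted p = 0.470, and adjusted p = 0.712 with an estimated correlation). This list shares MMP9 and mmp13a with the metalloproteinases. At 2 dpa MMP9 stood at 156 to 321 CPM (78.2 to 135 at 0 dpa) and mmp13a at 38.7 to 78.4 CPM (10.5 to 19.4). The member npsn stood at 7.45 to 29.8 CPM (56.5 to 65.8 at 0 dpa).

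At 2 dpa 7821 genes passed, 3811 higher and 4010 lower, and of these 2531 were at least 2-fold higher and 3142 at least 2-fold lower. The 3 libraries of one stage lay entirely above or below those of the other for 54.6% of tested genes, where chance gives 10%. Within the 2 dpa group, replicate 2 differed from the others in several genes named here. FN1 (ENSDARG00000006526) stood at 16508 CPM there against 41823 and 41795 in replicates 1 and 3, and krt18a.1 at 7985 against 20442 and 17764.

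**Figure D3:**
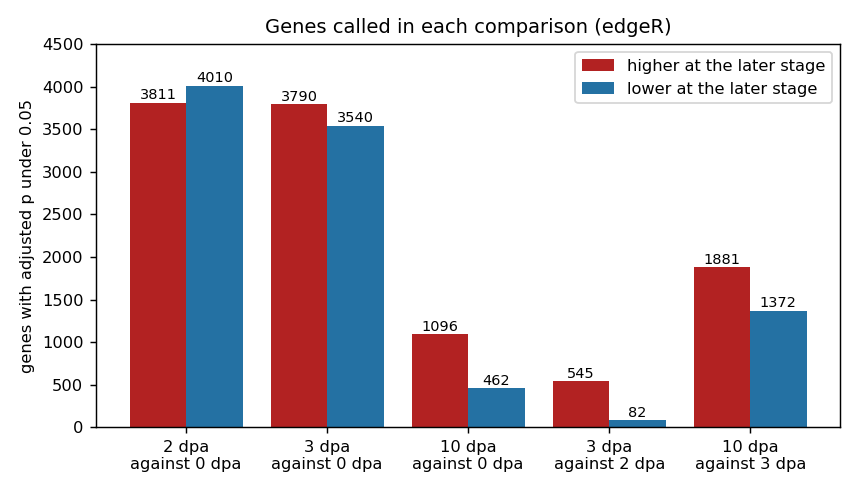
Bars give the number of genes with an adjusted p under 0.05 (edgeR, of 16612 tested) in each of the 5 comparisons, higher (red) or lower (blue) at the later stage. Counts are 3811 and 4010 for 2 dpa and 3790 and 3540 for 3 dpa against the uncut fin, 1096 and 462 for 10 dpa against the uncut fin, 545 and 82 for 3 against 2 dpa, and 1881 and 1372 for 10 against 3 dpa.

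The comparison of 3 dpa with the uncut fin asked the same a day later. Among the largest rises, the secretory calcium-binding phosphoprotein genes scpp5 (ENSDARG00000078622) and scpp7 (ENSDARG00000074132) rose from 0.714 ± 1.02 to 98.5 ± 13.7 CPM (adjusted p = 2.78e-05) and from 0.613 ± 0.393 to 47.9 ± 29.2 CPM (adjusted p = 9.69e-05). The enamelin gene enam (ENSDARG00000092730) rose from 19.3 ± 17.5 to 2279 ± 1010.3 CPM. All 3 measured members of the actinotrichia list rose, and1 from 543 ± 358 to 23619 ± 10583 CPM, and2 (ENSDARG00000079302) from 75.2 ± 57.4 to 6370.3 ± 2151 CPM and and3 from 1.64 ± 0.524 to 6.63 ± 3.44 CPM. The signal il11a was 32.7-fold higher at 13.4 ± 2.24 CPM. Among the largest falls, prg4a went from 931 ± 167 to 3.62 ± 2.53 CPM and the chemokine gene ccl27b from 95.9 ± 42.2 to 0.538 ± 0.307 CPM.

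Fibrillar collagens and collagen maturation enzymes were higher as lists at 3 dpa, while the other collagens did not pass. Of the fibrillar collagens, 10 of 11 rose (10 adjusted over the list alone) (list adjusted p = 2.56e-04, and adjusted p = 0.550 with an estimated correlation). The type I collagen gene col1a1a rose from 8248 ± 6569 to 45827 ± 7918 CPM and col11a1b from 127 ± 124 to 934 ± 147 CPM. Among collagen maturation enzymes, 23 of 30 rose and 3 fell (24 and 3 adjusted over the list alone) (list adjusted p = 1.19e-07, and adjusted p = 0.399 with an estimated correlation). SERPINH1 (ENSDARG00000075954) rose 13.5-fold, FKBP9 11.7-fold and the lysyl hydroxylase PLOD1 8.86-fold, and pcolceb fell from 236 ± 35.3 to 11.0 ± 4.79 CPM. Metalloproteinases and inhibitors were higher as a list, where 18 of 30 rose and 3 fell (18 and 3 adjusted over the list alone) (list adjusted p = 2.57e-04, and adjusted p = 0.356 with an estimated correlation). ADAMTS18 and MMP24 were 21.1-fold and 17.1-fold higher, and mmp30 fell from 69.0 ± 27.3 to 8.13 ± 2.40 CPM. The osteoblast and bone matrix list did not pass, although 12 of 26 rose and 4 fell (13 and 4 adjusted over the list alone) (list adjusted p = 0.137, 0.0405 to 0.247 over 10 other settings of which 1 passed, and adjusted p = 0.712 with an estimated correlation). The osteoblast channel PANX3 rose from 13.7 ± 12.0 to 149.6 ± 57.9 CPM. Matrix Gla protein (mgp), an inhibitor of calcification, fell from 13.5 ± 6.34 to 0.409 ± 0.372 CPM and osteopontin (spp1) from 86.5 ± 32.4 to 33.3 ± 5.58 CPM. Of the ECM glycoproteins, 12 of 32 rose and 5 fell (12 and 6 adjusted over the list alone) (list adjusted p = 0.0664, 0.0211 to 0.145 over 10 other settings of which 4 passed, and adjusted p = 0.711 with an estimated correlation). For the basement membrane list, 14 of 31 rose and 7 fell (14 and 7 adjusted over the list alone) (list adjusted p = 0.0720, 0.0459 to 0.189 over 10 other settings of which 1 passed, and adjusted p = 0.650 with an estimated correlation). Of the proteoglycans, 10 of 25 rose and 8 fell (10 and 8 adjusted over the list alone) (list adjusted p = 0.770, and adjusted p = 0.963 with an estimated correlation). Of the other collagens, 6 of 17 rose and 5 fell (6 and 5 adjusted over the list alone) (list adjusted p = 0.704, and adjusted p = 0.934 with an estimated correlation).

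Proliferation and secretion genes stood above the uncut fin at 3 dpa as well. Of the cell cycle list, 53 of 57 rose (55 adjusted over the list alone) (list adjusted p = 1.43e-18, and adjusted p = 0.263 with an estimated correlation), and aurka rose 12.1-fold to 11.3 ± 1.24 CPM. In the secretory pathway list, 34 of 41 rose and 1 fell (35 and 1 adjusted over the list alone) (list adjusted p = 5.41e-12, and adjusted p = 0.128 with an estimated correlation). The cargo receptor LMAN1, which carries glycoproteins out of the endoplasmic reticulum, was 9.60-fold and the disulfide isomerase PDIA6 5.28-fold higher. Of the ribosome biogenesis genes, 14 of 28 rose and 1 fell (14 and 1 adjusted over the list alone) (list adjusted p = 0.00275, and adjusted p = 0.599 with an estimated correlation), with DKC1, the pseudouridine synthase dyskerin, 3.23-fold higher. Blastema and fin outgrowth signals passed as a list, where 29 of 60 rose and 5 fell (29 and 6 adjusted over the list alone) (list adjusted p = 9.38e-05, and adjusted p = 0.328 with an estimated correlation). The zinc finger factor SALL1 (ENSDARG00000075891) rose 20.9-fold. WNT3A fell from 8.79 ± 4.08 to 1.86 ± 0.328 CPM and the Notch ligand jag1b from 174 ± 22.0 to 64.2 ± 4.75 CPM.

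Pigment, glial, epidermal and mucous cell markers were lower at 3 dpa. Among pigment cell markers, 1 of 23 rose and 16 fell (1 and 17 adjusted over the list alone) (list adjusted p = 6.10e-06, and adjusted p = 0.348 with an estimated correlation). The melanocortin receptor MC1R, which drives melanin synthesis, fell from 3.02 ± 0.940 to 0.129 ± 0.0200 CPM. Of the nerve and glia markers, 1 of 16 rose and 12 fell (1 and 12 adjusted over the list alone) (list adjusted p = 2.70e-04, and adjusted p = 0.128 with an estimated correlation), and myelin basic protein (mbpa) fell from 7.28 ± 1.36 to 0.252 ± 0.272 CPM. Epidermal keratins and junctions were lower as a list, where 4 of 39 rose and 22 fell (4 and 23 adjusted over the list alone) (list adjusted p = 3.10e-04, and adjusted p = 0.457 with an estimated correlation). Of these krt1-19d fell from 809 ± 107 to 209.5 ± 67.8 CPM, while krt18a.1 stood 8.13-fold higher. Of the goblet cell and ionocyte markers, 4 of 16 rose and 11 fell (4 and 11 adjusted over the list alone) (list adjusted p = 0.0422, and adjusted p = 0.399 with an estimated correlation). The mucin muc5.2 fell from 23.2 ± 6.83 to 1.66 ± 0.280 CPM and the ionocyte factor foxi3b from 2.34 ± 0.398 to 0.154 ± 0.0744 CPM. The goblet cell list did not pass in the paired fit with a replicate block (adjusted p = 0.0576), with RLE normalisation (0.0507) and without 0 dpa replicate 1 (0.0720), 0 dpa replicate 3 (0.108), 3 dpa replicate 1 (0.0734) or 3 dpa replicate 2 (0.0715). Its adjusted p ran from 0.00798 to 0.108 over the settings with the preset correlation. Of the endothelial and lymphatic markers, 2 of 24 rose and 5 fell (1 and 5 adjusted over the list alone) (list adjusted p = 0.775, and adjusted p = 0.963 with an estimated correlation). Of the erythrocyte markers, 2 of 11 fell (2 adjusted over the list alone) (list adjusted p = 0.168, 0.0188 to 0.308 over 10 other settings of which 1 passed, and adjusted p = 0.708 with an estimated correlation).

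At 3 dpa 7330 genes passed, 3790 higher and 3540 lower, of which 2663 were at least 2-fold higher and 2666 at least 2-fold lower. Which direction had more genes depended on the processing, since fewer were higher than lower with RLE normalisation (3535 and 3790), with DESeq2 (3699 and 4029), with no filter (3539 and 3617) and with the 2 compared groups alone (3697 and 3747). Libraries of both stages did not overlap for 56.4% of tested genes, where chance gives 10%. Within the 0 dpa group, replicate 3 stood above replicates 1 and 2 in several collagen genes, with col1a1a at 15623 CPM against 6094 and 3026 and col11a1b at 267 against 79.2 and 33.7. Without that library their log2 changes at 3 dpa were 3.33 and 4.05, against 2.47 and 2.88 with it.

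**Figure D4:**
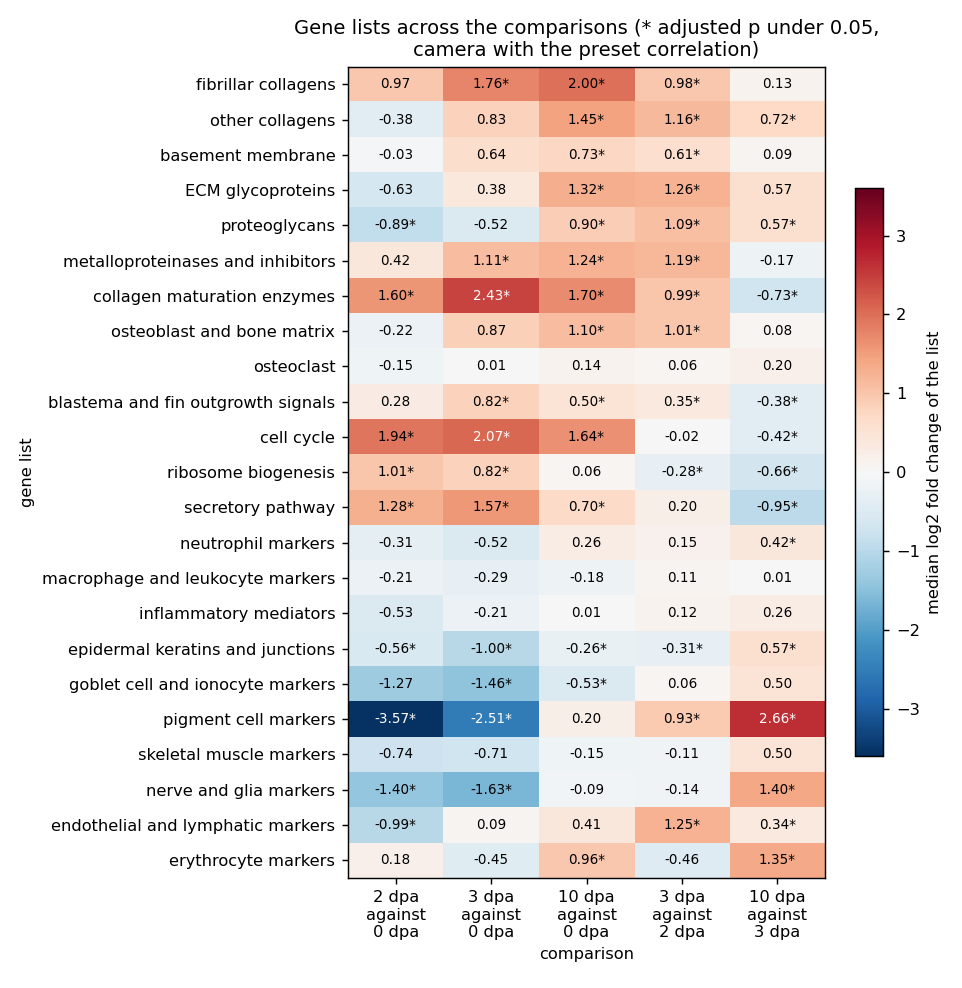
Each cell gives the median log2 fold change of the tested members of a gene list (vertical axis) in a comparison (horizontal axis), on a colour scale from blue (lower at the later stage) to red (higher), and an asterisk marks an adjusted p under 0.05 by camera with the preset correlation, a call that no list kept with an estimated correlation. Pigment cell markers range from -3.57 at 2 dpa against 0 dpa to 2.66 at 10 dpa against 3 dpa, and cell cycle genes stand at 1.94, 2.07 and 1.64 above the uncut fin at 2, 3 and 10 dpa.

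Fins at 10 dpa were compared with uncut fins to ask what still differed at the latest stage sampled. Levels of scpp5 went from 0.714 ± 1.02 to 31.2 ± 9.99 CPM (adjusted p = 0.00212), and those of and1 from 543 ± 358 to 5929.8 ± 2118 CPM (adjusted p = 0.00680). The gene slc13a5b, named for a citrate transporter, rose from 0.692 ± 0.609 to 22.1 ± 11.6 CPM (adjusted p = 0.00563). TNC (ENSDARG00000021948) and NID2 were 6.65-fold and 6.49-fold higher. The largest fall by the naming rule was in the lubricin gene prg4a (from 931 ± 167 to 56.8 ± 8.21 CPM, adjusted p = 6.63e-04). Arginase 2 (ARG2, ENSDARG00000039269) fell from 126 ± 54.0 to 19.5 ± 3.75 CPM (adjusted p = 9.54e-04), and the scaffold protein akap12a from 8.84 ± 1.52 to 1.29 ± 0.765 CPM (adjusted p = 0.00279).

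Matrix and bone lists were higher at 10 dpa. Of the fibrillar collagens, 9 of 11 rose (11 adjusted over the list alone) (list adjusted p = 1.83e-08, and adjusted p = 0.356 with an estimated correlation). Of the other collagens, 7 of 17 rose (11 rose and 1 fell adjusted over the list alone) (list adjusted p = 1.62e-04, and adjusted p = 0.408 with an estimated correlation). Among collagen maturation enzymes, 22 of 30 rose (26 adjusted over the list alone) (list adjusted p = 1.39e-15, and adjusted p = 0.263 with an estimated correlation). The lysyl hydroxylase PLOD2 rose from 7.45 ± 5.78 to 51.0 ± 9.03 CPM and the prolyl hydroxylase P4HA1 5.14-fold. Among the ECM glycoproteins, 12 of 32 rose (19 adjusted over the list alone) (list adjusted p = 1.35e-08, and adjusted p = 0.328 with an estimated correlation), and the microfibril protein mfap2 rose from 19.2 ± 14.3 to 104 ± 8.84 CPM. Of the metalloproteinases and inhibitors, 13 of 30 rose (19 adjusted over the list alone) (list adjusted p = 3.76e-08, and adjusted p = 0.237 with an estimated correlation). MMP15 (ENSDARG00000013072) was 6.51-fold and ADAMTS18 7.02-fold higher. In the basement membrane list, 8 of 31 rose and 1 fell (14 and 1 adjusted over the list alone) (list adjusted p = 6.78e-05, and adjusted p = 0.356 with an estimated correlation). For osteoblast and bone matrix genes, 13 of 26 rose and 1 fell (16 and 2 adjusted over the list alone) (list adjusted p = 1.16e-04, and adjusted p = 0.399 with an estimated correlation). Of the proteoglycans, 8 of 25 rose and 1 fell (14 and 4 adjusted over the list alone) (list adjusted p = 0.0379, and adjusted p = 0.650 with an estimated correlation). The proteoglycan list did not pass in the paired fit with a replicate block (adjusted p = 0.0614) or without 0 dpa replicate 2 (0.0735), 0 dpa replicate 3 (0.0908) or 10 dpa replicate 1 (0.0999). Over the settings with the preset correlation the proteoglycans' adjusted p ran from 0.00664 to 0.0999.

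Cell cycle genes were still above the uncut fin at 10 dpa. Of them, 42 of 57 rose (54 adjusted over the list alone) (list adjusted p = 9.35e-32, and adjusted p = 0.174 with an estimated correlation), with CCNB1 6.44-fold, kif11 5.96-fold and aurka 5.88-fold higher. In the secretory pathway list, 15 of 41 rose (21 adjusted over the list alone) (list adjusted p = 5.03e-07, and adjusted p = 0.237 with an estimated correlation). LMAN1 and the retrieval receptor KDELR3 were 4.06-fold and 2.94-fold higher. Of the blastema and fin outgrowth signals, 13 of 60 rose and 1 fell (20 and 2 adjusted over the list alone) (list adjusted p = 1.80e-04, and adjusted p = 0.348 with an estimated correlation). Of the ribosome biogenesis genes, 1 of 28 fell (1 adjusted over the list alone) (list adjusted p = 0.505, 0.00696 to 0.811 over 10 other settings of which 1 passed, and adjusted p = 0.922 with an estimated correlation), the fall being that of DDX21 (from 143 ± 25.4 to 63.6 ± 12.0 CPM).

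Few markers of differentiated cells passed at 10 dpa, when 9.38% of all tested genes passed. Few passing markers therefore neither set these lists apart from other genes nor show a return to the uncut level. Of the pigment cell markers, 1 of 23 fell (1 adjusted over the list alone) (list adjusted p = 0.855, and adjusted p = 0.981 with an estimated correlation). The receptor KIT, which melanocytes need, was the member that fell (from 157 ± 28.5 to 62.6 ± 8.92 CPM). Of the nerve and glia markers, 0 of 16 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone, 0 and 2 at an unadjusted p under 0.05, and 0 and 1 by DESeq2) (list adjusted p = 0.399, and adjusted p = 0.599 with an estimated correlation). Of the endothelial and lymphatic markers, 3 of 24 rose (4 adjusted over the list alone) (list adjusted p = 0.0594, 0.0169 to 0.273 over 10 other settings of which 4 passed, and adjusted p = 0.678 with an estimated correlation). Epidermal keratins and junctions were lower as a list, where 1 of 39 rose and 3 fell (1 and 3 adjusted over the list alone) (list adjusted p = 0.0210, and adjusted p = 0.638 with an estimated correlation). They did not pass without 0 dpa replicate 1 (adjusted p = 0.0967), 10 dpa replicate 1 (0.0542) or 10 dpa replicate 3 (0.0730), with 2.32e-04 to 0.0967 over the settings with the preset correlation. Goblet cell and ionocyte markers were lower as a list too, where 1 of 16 rose and 3 fell (1 and 5 adjusted over the list alone) (list adjusted p = 0.0323, and adjusted p = 0.399 with an estimated correlation). That list did not pass without 0 dpa replicate 1 (adjusted p = 0.0668), 0 dpa replicate 3 (0.160) or 10 dpa replicate 1 (0.0542), with 5.97e-04 to 0.160 over the settings with the preset correlation. Of the inflammatory mediators, 1 of 24 rose and 1 fell (3 and 1 adjusted over the list alone) (list adjusted p = 0.721, 0.0312 to 0.988 over 10 other settings of which 1 passed, and adjusted p = 0.934 with an estimated correlation). Of the neutrophil markers, 1 of 13 rose (2 adjusted over the list alone) (list adjusted p = 0.165, 0.0457 to 0.321 over 10 other settings of which 2 passed, and adjusted p = 0.558 with an estimated correlation). Of the macrophage and leukocyte markers, 1 of 31 rose and 2 fell (2 and 4 adjusted over the list alone) (list adjusted p = 0.274, and adjusted p = 0.708 with an estimated correlation).

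At 10 dpa 1558 genes passed, 1096 higher and 462 lower than in the uncut fin. The libraries of both stages did not overlap for 33.9% of tested genes, where chance gives 10%. The count was 578 without 0 dpa replicate 1, 483 without 0 dpa replicate 2, 977 without 10 dpa replicate 1, 732 without 10 dpa replicate 2 and 751 without 10 dpa replicate 3. It was 721 (501 higher and 220 lower) with the second sequencing batch left out, a setting chosen after seeing the data, and 2343 (1363 higher and 980 lower) with DESeq2.

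Between 2 and 3 dpa the question was what changed within a day, and most genes that passed were higher at 3 dpa. The largest rises were in ccn1l1, named for a matricellular protein (from 0.0503 ± 0.0871 to 5.31 ± 1.86 CPM, adjusted p = 9.86e-04), and GDF5 (from 0.0335 ± 0.0580 to 1.67 ± 1.09 CPM, adjusted p = 0.00627). CYP2R1 (ENSDARG00000056587), a vitamin D 25-hydroxylase, rose from 2.95 ± 2.00 to 78.8 ± 37.8 CPM (adjusted p = 0.00117), and scpp5 from 4.00 ± 3.31 to 98.5 ± 13.7 CPM (adjusted p = 0.00394). Lysyl oxidase (LOX, ENSDARG00000003259), which cross-links collagen, rose from 11.3 ± 2.15 to 129.6 ± 55.6 CPM (adjusted p = 0.00222). LOXL1 rose 7.61-fold (log2 change 2.93 ± 0.28, adjusted p = 9.27e-04) and CXCL12 5.25-fold (adjusted p = 0.00183). The largest fall by the naming rule was in si:dkey-6n3.3 (ENSDARG00000095820), from 2.75 ± 1.48 to 0.169 ± 0.0818 CPM (adjusted p = 0.00838). It did not pass without 3 dpa replicate 3 (adjusted p = 0.0502, with 4.30e-05 to 0.0502 over all settings).

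Matrix lists were higher at 3 than at 2 dpa. Among collagen maturation enzymes, 7 of 30 rose (18 adjusted over the list alone) (list adjusted p = 2.37e-12, and adjusted p = 0.328 with an estimated correlation). Among the ECM glycoproteins, 6 of 32 rose and 1 fell (19 and 2 adjusted over the list alone) (list adjusted p = 3.27e-09, and adjusted p = 0.302 with an estimated correlation). For metalloproteinases and inhibitors, 11 of 30 rose (16 rose and 1 fell adjusted over the list alone) (list adjusted p = 5.04e-08, and adjusted p = 0.237 with an estimated correlation). Of the proteoglycans, 9 of 25 rose (12 adjusted over the list alone) (list adjusted p = 1.31e-06, and adjusted p = 0.355 with an estimated correlation). Of the other collagens, 3 of 17 rose (6 adjusted over the list alone) (list adjusted p = 2.08e-06, and adjusted p = 0.355 with an estimated correlation), and COL8A2 rose from 1.47 ± 0.230 to 7.88 ± 3.85 CPM. For osteoblast and bone matrix genes, 7 of 26 rose and 1 fell (16 and 1 adjusted over the list alone) (list adjusted p = 3.02e-09, and adjusted p = 0.263 with an estimated correlation). The fibrillar collagens passed as a list (list adjusted p = 9.38e-05, and adjusted p = 0.506 with an estimated correlation) although of its members 0 of 11 rose and 0 fell by edgeR (3 and 0 adjusted over the list alone, 6 and 0 at an unadjusted p under 0.05, and 1 and 0 by DESeq2). COL11A1 stood at 433 ± 30.6 CPM at 3 dpa and 190.1 ± 73.4 at 2 dpa. In the basement membrane list, 4 of 31 rose and 1 fell (9 and 1 adjusted over the list alone) (list adjusted p = 0.00219, and adjusted p = 0.457 with an estimated correlation), and the matricellular protein SMOC2 rose from 0.282 ± 0.137 to 2.33 ± 0.800 CPM. When the 2 compared groups alone were fitted, COL8A2 did not pass (adjusted p = 0.0712, with 1.18e-06 to 0.0712 over all settings), nor did SMOC2 (0.0653, with 5.90e-06 to 0.0653).

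Vessel and pigment markers were higher at 3 than at 2 dpa. Of the endothelial and lymphatic markers, 11 of 24 rose (17 adjusted over the list alone) (list adjusted p = 1.39e-13, and adjusted p = 0.203 with an estimated correlation). The gene plvapb, for a protein of capillary fenestrae, rose from 16.6 ± 8.37 to 64.0 ± 11.6 CPM, and the endothelial factor sox18 from 9.00 ± 2.48 to 33.5 ± 13.9 CPM. Fitted with the 2 compared groups alone, plvapb and sox18 did not pass (adjusted p = 0.0653 and 0.0744, with 4.19e-06 to 0.0653 and 1.92e-05 to 0.0744 over all settings). Of the pigment cell markers, 3 of 23 rose and 1 fell (11 and 1 adjusted over the list alone) (list adjusted p = 1.62e-04, and adjusted p = 0.399 with an estimated correlation). Of the blastema and fin outgrowth signals, 11 of 60 rose and 6 fell (19 and 7 adjusted over the list alone) (list adjusted p = 0.00212, and adjusted p = 0.399 with an estimated correlation). Cell cycle genes did not pass as a list, and 0 of 57 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone, 1 and 0 at an unadjusted p under 0.05, and 0 and 0 by DESeq2) (list adjusted p = 0.543, and adjusted p = 0.934 with an estimated correlation). Epidermal keratins and junctions were lower as a list, where 1 of 39 rose and 3 fell (1 and 4 adjusted over the list alone) (list adjusted p = 0.00521, and adjusted p = 0.584 with an estimated correlation). They did not pass without 2 dpa replicate 3 (adjusted p = 0.191, with 5.79e-06 to 0.191 over the settings with the preset correlation). Ribosome biogenesis genes were lower as a list (list adjusted p = 7.81e-04, and adjusted p = 0.566 with an estimated correlation), although of its members 0 of 28 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone, 0 and 5 at an unadjusted p under 0.05, and 0 and 1 by DESeq2). The ribosome list did not pass without 2 dpa replicate 2 (adjusted p = 0.128, with 5.77e-06 to 0.128 over the settings with the preset correlation).

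From 2 to 3 dpa 627 genes passed, 545 higher and 82 lower, and 18.3% of tested genes did not overlap between the stages, where chance gives 10%. The count was 1393 (1101 higher and 292 lower) without 2 dpa replicate 2, the library that stood toward 3 dpa. It was 226 without 2 dpa replicate 1, 186 without 2 dpa replicate 3, 259 without 3 dpa replicate 1 and 173 without 3 dpa replicate 3. With the second sequencing batch left out, a setting chosen after seeing the data, it was 1367 (1057 higher and 310 lower). It was 995 (776 and 219) with DESeq2 and 36 (30 and 6) when the 2 compared groups alone were fitted.

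The comparison of 10 with 3 dpa asked what changed over the later part of the course. Among the largest rises, the gene si:dkey-183i3.5 (ENSDARG00000056248) rose 135-fold to 1025 ± 354 CPM (adjusted p = 8.69e-07). The hemidesmosome collagen col17a1a rose 30.6-fold to 949.7 ± 23.7 CPM (log2 change 4.94 ± 0.28, adjusted p = 8.69e-07). Among the falls, il11a was 16.8-fold lower (adjusted p = 6.50e-06) and lepb 12.4-fold (adjusted p = 1.05e-04). FREM3 and the histamine receptor gene hrh3 were 16.9-fold (adjusted p = 5.79e-04) and 16.9-fold lower (adjusted p = 5.51e-05).

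Pigment and nerve markers were higher at 10 than at 3 dpa. Of the pigment cell markers, 17 of 23 rose and 1 fell (18 and 2 adjusted over the list alone) (list adjusted p = 2.39e-09, and adjusted p = 0.241 with an estimated correlation), and pmela was 19.1-fold higher at 164 ± 31.3 CPM. Of the nerve and glia markers, 10 of 16 rose and 1 fell (12 and 1 adjusted over the list alone) (list adjusted p = 7.32e-06, and adjusted p = 0.0997 with an estimated correlation), and mbpa rose from 0.252 ± 0.272 to 7.34 ± 2.33 CPM. Of the erythrocyte markers, 5 of 11 rose (5 adjusted over the list alone) (list adjusted p = 2.57e-04, and adjusted p = 0.356 with an estimated correlation). The carbonic anhydrase cahz rose 4.96-fold and alas2, the first enzyme of heme synthesis in red cells, 3.00-fold. Among epidermal keratins and junctions, 12 of 39 rose and 4 fell (15 and 4 adjusted over the list alone) (list adjusted p = 0.00276, and adjusted p = 0.566 with an estimated correlation), with krt1-19d 3.39-fold higher and krt18a.1 3.88-fold lower. Of the goblet cell and ionocyte markers, 4 of 16 rose and 2 fell (4 and 2 adjusted over the list alone) (list adjusted p = 0.284, and adjusted p = 0.650 with an estimated correlation), with muc5.2 8.41-fold higher. Endothelial and lymphatic markers were higher as a list, where 4 of 24 rose (4 adjusted over the list alone) (list adjusted p = 0.0306, and adjusted p = 0.638 with an estimated correlation), with vwf 5.52-fold higher. The endothelial list did not pass without 3 dpa replicate 2 (adjusted p = 0.108) or with the second sequencing batch left out (0.0622), with 0.0139 to 0.108 over the settings with the preset correlation. Neutrophil markers were higher as a list, where 3 of 13 rose and 1 fell (4 and 1 adjusted over the list alone) (list adjusted p = 0.0412, and adjusted p = 0.399 with an estimated correlation), with the cytokine receptor CSF3R 2.22-fold higher. The neutrophil list did not pass without 3 dpa replicate 2 (adjusted p = 0.0802), 10 dpa replicate 1 (0.0609) or 10 dpa replicate 3 (0.0772), with 0.0120 to 0.0802 over the settings with the preset correlation.

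Secretory genes were lower at 10 than at 3 dpa, while for cell cycle genes a lower level rested on the camera list test. In the secretory pathway list, 26 of 41 fell (34 fell and 1 rose adjusted over the list alone) (list adjusted p = 2.37e-12, and adjusted p = 0.128 with an estimated correlation). SEC61B, a subunit of the translocation channel, was 2.67-fold and KDELR2 2.56-fold lower. Of the ribosome biogenesis genes, 1 of 28 rose and 10 fell (1 and 15 adjusted over the list alone) (list adjusted p = 3.32e-06, and adjusted p = 0.399 with an estimated correlation). Of the cell cycle list, 7 of 57 fell (2 adjusted over the list alone) (list adjusted p = 3.62e-04, and adjusted p = 0.607 with an estimated correlation). Its median log2 change was -0.421, and fry did not pass it (unadjusted p = 0.0836). Of all tested genes, 19.6% passed in this comparison, so the number of passing members does not set the cell cycle list apart. Of the blastema and fin outgrowth signals, 5 of 60 rose and 20 fell (6 and 22 adjusted over the list alone) (list adjusted p = 3.66e-04, and adjusted p = 0.356 with an estimated correlation). SALL1 (ENSDARG00000075891) was 6.46-fold lower and jag1b 1.76-fold higher.

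Matrix genes moved in both directions between 3 and 10 dpa. Collagen maturation enzymes were lower as a list, where 4 of 30 rose and 9 fell (4 and 12 adjusted over the list alone) (list adjusted p = 0.0399, and adjusted p = 0.712 with an estimated correlation). FKBP9 was 3.06-fold lower and pcolceb 17.2-fold higher. The enzyme list did not pass without 3 dpa replicate 1 (adjusted p = 0.110), 3 dpa replicate 3 (0.0546) or 10 dpa replicate 1 (0.0693), with 0.00288 to 0.110 over the settings with the preset correlation. Other collagens were higher as a list, where 5 of 17 rose (6 rose and 1 fell adjusted over the list alone) (list adjusted p = 0.0201, and adjusted p = 0.607 with an estimated correlation), with COL8A2 10.1-fold higher. They did not pass without 10 dpa replicate 2 (adjusted p = 0.104) or with the second sequencing batch left out (0.0669), with 0.00825 to 0.104 over the settings with the preset correlation. Proteoglycans were higher as a list, where 9 of 25 rose and 2 fell (10 and 3 adjusted over the list alone) (list adjusted p = 0.0188, and adjusted p = 0.607 with an estimated correlation), with PODN 29.7-fold higher. That list did not pass without 3 dpa replicate 2 (adjusted p = 0.0539, with 0.00865 to 0.0539 over the settings with the preset correlation). For osteoblast and bone matrix genes, 4 of 26 rose and 3 fell (5 and 4 adjusted over the list alone) (list adjusted p = 0.431, and adjusted p = 0.860 with an estimated correlation). Osteopontin (spp1) rose 9.40-fold to 312 ± 43.1 CPM, and the factor DLX5 was 2.22-fold lower. Of the fibrillar collagens, 0 of 11 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone, 0 and 0 at an unadjusted p under 0.05, and 0 and 0 by DESeq2) (list adjusted p = 0.956, and adjusted p = 0.981 with an estimated correlation). Among the ECM glycoproteins, 7 of 32 rose and 5 fell (7 and 5 adjusted over the list alone) (list adjusted p = 0.169, and adjusted p = 0.749 with an estimated correlation). In the basement membrane list, 7 of 31 rose and 8 fell (7 and 9 adjusted over the list alone) (list adjusted p = 0.956, and adjusted p = 0.981 with an estimated correlation). For metalloproteinases and inhibitors, 6 of 30 rose and 10 fell (6 and 11 adjusted over the list alone) (list adjusted p = 0.236, and adjusted p = 0.712 with an estimated correlation).

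Between 3 and 10 dpa 3253 genes passed, 1881 higher and 1372 lower, with 39.5% of tested genes not overlapping between the stages, where chance gives 10%. The count was 2155 without 3 dpa replicate 2 and 2078 without 10 dpa replicate 3.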

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

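The second sequencing batch was left out, and other splits of the samples were counted, only after the data had been seen. Counts for 2 dpa (7821) and 3 dpa (7330) against the uncut fin and for the 4 stages (8090) stayed within 1.5 times under every setting run. For 3 against 2 dpa (627) the count was 36 with the 2 compared groups alone, 995 with DESeq2, 1367 without the second batch, and 173 to 1393 with 1 library left out. For 10 against 0 dpa (1558) it was 2343 with DESeq2, 721 without the second batch and 483 to 1462 with 1 library left out. For 10 against 3 dpa (3253) it was 2078 to 2373 with 1 library left out. Fitted with the compared groups alone, both comparisons with 2 dpa gave fewer genes (6590 for 2 against 0 dpa and 36 for 3 against 2 dpa). The others gave more (7444 for 3 against 0 dpa, 2298 for 10 against 0 dpa and 3472 for 10 against 3 dpa). The main fit shares its estimate of spread across stages, and the largest chi-square between replicates (123) was at 2 dpa. The cause of these moves was not tested.

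In the paired fit with a replicate block the counts were 8477, 8085, 2289, 700 and 4016 for the 5 comparisons and 9087 for the 4 stages. It ended 2 list calls (goblet cell and ionocyte markers at 3 dpa and proteoglycans at 10 dpa, both against 0 dpa) and 17 of 520 calls of named genes, and 6 named gene results came to pass. It changed no other call among the lists and named genes.

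Of the 60 gene list tests that passed, 0 passed with an estimated correlation by camera (18 of 115 at an unadjusted p under 0.05), while 48 of them passed with fry, which passed 54 of all 115. RLE normalisation gave 59, no filter 67, and leaving out the second batch 67, with 4 calls lost and 11 gained. No list call reversed under these settings. Fry did not pass the camera call of collagen maturation enzymes at 2 against 0 dpa. At 10 against 0 dpa it did not pass those of proteoglycans, erythrocyte and epidermal markers. At 3 against 2 dpa these were fibrillar collagens, ribosome biogenesis and epidermal markers. At 10 against 3 dpa they were cell cycle genes, other collagens, collagen maturation enzymes, epidermal and endothelial markers. For 12 list results, none of which passed, median, mean and test differed in sign: basement membrane (2 against 0 and 10 against 3 dpa), erythrocyte (2 against 0 dpa), endothelial (3 against 0 dpa), ribosome biogenesis (10 against 0 dpa), neutrophil and goblet cell (3 against 2 dpa), osteoclast (3 against 0 and 3 against 2 dpa) and skeletal muscle (3 against 0, 10 against 0 and 3 against 2 dpa). In 3 list results a member had 0 counts in a group, and a floor of 3 counts over the group moved their medians by 0. Fry, but not camera, passed blastema signals and goblet cell markers at 2 against 0 dpa. The same held for basement membrane and ECM glycoproteins at 3 against 0 dpa and the osteoclast list at 10 against 0 and 10 against 3 dpa. Of the 520 calls of named genes, leaving out some 1 library ended 156, no filter 55, RLE normalisation 11, leaving out the second batch 84 of 518, the compared groups alone 67 of 501 and DESeq2 5 of 516, and 0 reversed.

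For each comparison of 2 stages, the 10 splits of its 6 libraries were too few for a share under 0.05. Only 1 split, the real one, gave as many genes. In every other split both groups held libraries of both stages, so any stage difference widened the spread and lowered the count. Low counts in those splits therefore do not measure false calls among the genes that passed. The real counts and the highest of the other splits were 7821 and 0 (2 against 0 dpa), 7330 and 0 (3 against 0 dpa), 1558 and 1 (10 against 0 dpa), 627 and 0 (3 against 2 dpa) and 3253 and 0 (10 against 3 dpa). Of the 10 splits, 4 part every same-numbered pair, and the highest of their other counts was 0. For the 4 stages, 1 of 100 splits, the real one, gave 8090 genes, and the highest other gave 6856. That share, the lowest that 100 splits can give, argues against a chance split as the source of the count as a whole. It does not test any single gene. Among 40 splits that kept each replicate number once per group, the highest other gave 4056. At these depths genes of 3 or fewer counts in a group were given no fold.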

Other observations

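All tests in the last 2 paragraphs were chosen after the result, or a closely related value, had been seen, while the list tests were planned. Erythrocyte, osteoclast and muscle markers have so far been described only in part. Of the erythrocyte markers at 2 dpa against 0 dpa, 3 of 11 fell (3 adjusted over the list alone) (list adjusted p = 0.695, and adjusted p = 0.928 with an estimated correlation). At 10 dpa the erythrocyte list was higher than in the uncut fin (list adjusted p = 0.0364, and adjusted p = 0.584 with an estimated correlation), although of its members 0 of 11 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone, 4 and 0 at an unadjusted p under 0.05, and 1 and 0 by DESeq2). That call ended without 0 dpa replicate 2 (adjusted p = 0.0735), 0 dpa replicate 3 (0.102) or 10 dpa replicate 3 (0.137), with 0.0115 to 0.137 over the settings with the preset correlation. Of the osteoclast list, 3 of 9 rose and 3 fell (3 and 3 adjusted over the list alone) at 2 dpa (list adjusted p = 0.971, and adjusted p = 0.981 with an estimated correlation). Tartrate-resistant acid phosphatase (ACP5) rose from 7.54 ± 3.70 to 58.9 ± 18.5 CPM, while TCIRG1, a subunit of the proton pump, fell from 9.19 ± 0.910 to 0.485 ± 0.260 CPM. At 10 dpa, 3 of 9 rose (3 adjusted over the list alone) on that list (list adjusted p = 0.216, and adjusted p = 0.584 with an estimated correlation). Of the skeletal muscle markers, 3 of 18 rose and 8 fell (3 and 9 adjusted over the list alone) at 2 dpa (list adjusted p = 0.444, and adjusted p = 0.766 with an estimated correlation). The troponin gene TNNT3 (ENSDARG00000068457) was among those that rose, from 0.571 ± 0.147 to 7.31 ± 1.99 CPM.

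Some genes of one symbol or one list moved in opposite directions. Both genes named EDNRB, an endothelin receptor of pigment cell precursors, changed at 2 dpa. One (ENSDARG00000089334) fell from 15.3 ± 2.25 to 0.270 ± 0.235 CPM (adjusted p = 6.42e-07) and the other (ENSDARG00000053498) rose from 1.16 ± 0.575 to 44.3 ± 17.5 CPM (adjusted p = 8.12e-07). By 10 dpa they averaged 12.0 ± 1.92 and 2.22 ± 0.411 CPM. On the nerve and glia list, where 10 of 16 members fell at 2 dpa, STMN2 (ENSDARG00000070537), a microtubule regulator of growing neurites, rose from 1.25 ± 0.583 to 14.6 ± 5.25 CPM. It averaged 1.66 ± 0.900 CPM at 10 dpa.

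The 2 dpa library of replicate 2 lay at 0.498 on an axis of 1363 genes on which replicates 1 and 3 average 0 at 2 dpa and 1 at 3 dpa. Against a sequencing batch shared by the replicate 2 libraries as the whole source, those of 0 and 10 dpa, stages outside the choice of these genes, did not move with it along the axis (-0.127 and -0.0336). That of 3 dpa moved by -0.216, which is not weighed here because held-out libraries are drawn inward. Over all genes, however, the replicate 2 libraries of 2, 3 and 10 dpa deviated together from their stage means (r = 0.251 for 2 and 3 dpa, 0.322 for 2 and 10 dpa and 0.478 for 3 and 10 dpa, while that of 0 dpa gave -0.225, 0.0553 and -0.0282 with those of 2, 3 and 10 dpa), so a share of such a batch in the place of this library stays open. Against a swap with the 3 dpa pool, 3 dpa replicate 2 lay at 0.784, nearer to 3 dpa. Against uncut tissue in the pool, 239 genes at least 4-fold lower at 2 and 3 dpa had a median log2 difference of -0.187 (quartiles -0.641 to 0.274) from the other 2 dpa libraries, where such tissue would raise them. These genes were chosen without the replicate 2 libraries. They averaged at least 1 CPM in 2 dpa replicates 1 and 3, a filter that draws the held-out library down. On them 3 dpa replicate 2 differed by -0.341 and 10 dpa replicate 2 by 0.00787 from the others of their stage, so a small share of uncut tissue stays open. A candidate explanation is a pool further along the course, since genes higher and genes lower at 3 dpa placed it at 0.496 and 0.522, although the inward pull acts on this library too. RNA of both stages in 1 pool would place it there too and stays open, and the uncut libraries lie at 0.620 to 0.770, so the axis does not measure time alone.

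Markers of pigment, nerve and endothelial cells were lower at 2 dpa than before amputation. Against a few genes taking most of the counts, which would lower all others, the median log2 change of all tested genes in CPM without TMM factors ran from -0.0303 to 0.300 over the 9 pairs of a 2 dpa and a 0 dpa library. The median changes of the pigment, nerve and endothelial lists differed from it by -2.70, -0.931 and -0.706 or lower in every pair. Against equal dilution of all cell types of the uncut fin as the whole source, the pigment list fell further than the endothelial list in all 9 pairs, by a log2 difference of medians of -2.48 to -1.80. Dilution together with a rise of one of these cell types stays open. Fewer such cells in the sampled tissue and less RNA per cell cannot be told apart, since either may give the fall of 19 of 23 pigment markers and counts of pooled tissue hold no cell numbers. The stage after amputation, which sets what tissue is sampled, stays open and untested as their source.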
